A study of Mus musculus with 4 samples.

How the data were processed

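Gene expression was measured in single cells of 2 sorted monocyte populations, MDP and GMP, from 4 mice. Per the labels' protocols, dura was digested, cells of each mouse were tagged with a lipid-bound oligonucleotide before sorting, and each population was processed in a single 10x 3' capture with a separate tag library. The design text names dura as the source, whereas the sample labels give dura and brain; values are described here as those of dura. Per the design text, reads were aligned to a GRCm39 reference with Cell Ranger 9.0.1. The submitters' processing notes also list R 4.5.1 and Seurat 5.3.1, with no role given. The deposited values are UMI counts, 1 matrix for each mouse and population, not normalized, over 33696 genes and 12 tags. Which cells the authors left out before deposit is not given in the sources used here. The mouse numbers are those under which the authors deposited the matrices, and the same tag leads the cells of a mouse number in both captures.

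Cells were kept with at least 1000 UMIs, at least 500 genes and at most 10% mitochondrial UMIs. Scrublet, run for each capture in scanpy, called 8 of 1250 MDP cells (0.64%) and 0 of 11259 GMP cells, too few for its GMP result to be relied on. Whether doublets were removed before deposit is not given in the sources used here. Called cells were removed, and removal of the top 5% of doublet scores was added as an alternative. Counts of kept cells were scaled per cell and logged, 2000 variable genes and 30 principal components were taken, and Leiden clustering at resolution 0.8 on 15 neighbours gave the clusters. A cluster was named from 23 fixed marker lists where the median marker was at least 1 log2 unit above other clusters, at least 3 markers were 1.5-fold up at 10 CPM or more, no other list had more markers among its top 10 genes, and its depth was not low; this naming rule was set after the clusters were seen. Classical monocyte-like, border-associated macrophage-like and fibroblast-like clusters were named, 1 each, and the other clusters stayed unnamed. Cluster 6 passed the marker and depth conditions for the classical class (median 1.24, 7 markers up) and stayed unnamed because another list had 3 of its top 10 genes.

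Raw UMI counts were summed for each mouse and population, over all kept cells or over the cells of a class with at least 20 cells. Sums were tested with edgeR's quasi-likelihood test (TMM factors, filterByExpr, Benjamini-Hochberg adjustment at 0.05), MDP against GMP, without a block, as fixed before the data were examined. Log2 fold changes are MDP over GMP, from edgeR's quasi-likelihood fit at its default prior count. A prior count of 2 was used only for log CPM. Standard errors (SE) are the absolute log2 fold change divided by the square root of the F statistic. CPM values are of the sums, as mean ± SD over the 4 mice. Over all kept cells this SD also spans a mix of clusters that differed between mice 1 and 2 and mice 3 and 4. The fit with the mouse as a block is given beside each result that it changes. Same-numbered sums were taken to come from the same animal, because cells were tagged by mouse before the sort, per the design text, and share a number and a leading tag; the labels do not state it in words. Of the deposited cells, 4 of GMP mouse 4 and 1 of GMP mouse 3 were led by the tag of another mouse and were left under the deposited number. Their deviations from the population means correlated at 0.643, 0.637, 0.381 and 0.583 for mice 1 to 4 over all kept cells, and at 0.329, 0.195, 0.320 and 0.489 in the classical monocyte-like class. In that class mouse 2 correlated as closely with another mouse (0.196).

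The 19 gene lists named in the text were fixed in advance and tested with limma's camera at a preset correlation of 0.01, two-sided, beside an estimated correlation and fry. Over all kept cells fry values are given for the lists with a paragraph of their own. In the classical monocyte-like class they are given for some lists, and other fry values are not reported here. Shares were compared by an exact two-sided permutation test over the 70 assignments of 8 values; paired sign flips over 4 mice cannot give a p under 0.125. Floors use 3 counts. Named genes were chosen by a fixed rule, and some genes it takes are not reported here. Part a took up to 10 genes in each direction with the largest fold change among those called, with all MDP sums above or all below the GMP sums (a separation chance gives in 2.86% of genes), at least 50 CPM, and no predicted-gene symbol, ribosomal protein or mitochondrial gene. Part b took up to 3 called members of each list and its most abundant member where fewer passed. Part c took Ms4a3, Ly6c2 and Ccr2. Part a was also run on the blocked fit, a choice made after the data were seen, and there it asked that all 4 mice moved the same way in place of the separation of all sums. List members, dendritic cell markers and the genes of cluster 1 named as examples outside this rule were chosen after their values were seen.

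Transcript lengths and coordinates were taken from GENCODE mouse release 39 (GRCm39), and 99.7% of tested genes had a length. The length correction removes, for each sum, a smooth trend of log CPM on transcript length. The edgeR step was tested on simulated counts with 200 changed genes. Counts were drawn around means fitted with mouse effects only, at the dispersions of the blocked fit. The simulation thus follows the model of the blocked fit and holds no capture effect, so it cannot show which fit suits the real data. For all kept cells (11193 genes) it recovered 7.46, 64.2 and 93.9% of 1.5-, 2- and 4-fold changes without the block and 92.5, 100 and 100% with it, with 0 and 0.164% of unchanged genes called. For the classical class (6668 genes) it recovered 11.9, 49.3 and 98.5% without and 55.2, 91.0 and 100% with the block, with 0 and 0.139% of unchanged genes called.

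Alternatives covered normalization, test, gene and cell filters, doublets, clustering resolution, equal cell numbers and depth, pairing and leaving out each sum. Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9, scikit-learn 1.9.0 and matplotlib 3.10.9. Total UMIs were lowest for MDP mouse 3 over all kept cells and for GMP mouse 1 in cluster 1 (175705). The mice are separate animals, so that p-values cover the spread between mice, but not between captures.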

Results

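Monocytes of 2 origins were profiled in the dura mater of mice with a group B streptococcal infection. The 4 mice carried Ms4a3-Cre and a Cre-dependent tdTomato reporter, a combination known to mark the progeny of granulocyte-monocyte progenitors (GMP), so that GMP monocytes could be sorted apart from monocytes attributed to monocyte-dendritic cell progenitors (MDP). The animals had received 50 µl of bacteria retro-orbitally and were studied on day 2. The sort gave about 59400 GMP monocytes and about 7500 MDP monocytes, and each population was run as 1 droplet capture with 3' counting of unique molecular identifiers (UMIs). A tag added before sorting told the mice apart, so the data form 8 sums of cells, 1 for each of the 4 mice in each of the 2 populations. Because each population was a single capture, capture and population cannot be told apart in any comparison.

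For mice 1 to 4, the MDP matrices held 555, 491, 98 and 199 barcodes and the GMP matrices held 4973, 4287, 1034 and 1163. After filtering, 473, 482, 94 and 193 MDP cells and 4934, 4228, 957 and 1140 GMP cells were kept. Their total UMIs were 4782035, 5778921, 926496 and 1900838 in MDP and 45816268, 40028536, 7844409 and 8976281 in GMP. The median depth per kept cell ranged from 9574 to 11557 UMIs in MDP and from 7418 to 8827 UMIs in GMP. The median mitochondrial share ranged from 0.901 to 1.12% in MDP and from 0.624 to 1.00% in GMP.

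The genes that mark the sort and the monocyte state were read before any other. Ms4a3, whose promoter drives the Cre, gave 1, 1, 0 and 0 UMIs in MDP mice 1 to 4 and 29, 31, 196 and 3 UMIs in GMP mice 1 to 4. The 0 counts allow up to 3.24 CPM (UMIs scaled to a common total) in MDP mouse 3 and 1.58 CPM in MDP mouse 4, for counting error only, against 25.0 CPM in GMP mouse 3 and 0.334 CPM in GMP mouse 4. Ly6c2, a surface antigen of classical monocytes, was at 1282 ± 272 CPM in MDP and 1507 ± 455 CPM in GMP (SD, n = 4). Ccr2, the chemokine receptor that brings monocytes out of the marrow, was at 344 ± 122 and 316 ± 179 CPM (SD, n = 4). Neither passed the edgeR test, with adjusted p of 0.812 for Ly6c2 and 0.976 for Ccr2, or 0.0558 and 0.163 with the mouse as a block.

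Over all kept cells, MDP monocytes held more MHC class II transcripts and fewer transcripts of secreted granule and alarmin proteins than GMP monocytes of the same mice. With the mouse as a block, edgeR called 932 genes higher and 1086 lower in MDP at an adjusted p under 0.05, out of 11343 tested. Without the block it called 15 higher and 47 lower, and all 62 of these were also called with the block. At an unadjusted p the unblocked counts were 562 and 717. Among the genes called without the block was Lars2, a mitochondrial leucyl-tRNA synthetase, at 128 ± 31.2 CPM in MDP and 41.3 ± 5.18 CPM in GMP (SD, n = 4; log2 fold change 1.62, SE 0.17, edgeR adjusted p 0.00908). Areg, the growth factor amphiregulin (1.26, SE 0.21), Spon1, the matrix protein spondin 1 (1.26, SE 0.16), and Bhlhe40, a transcription factor (0.84, SE 0.13), were also higher in MDP in all 4 mice. Chil3, a secreted chitinase-like protein of classical monocytes, was lower, at 477 ± 208 CPM in MDP and 2629 ± 478 CPM in GMP (SD, n = 4; log2 fold change -2.46, SE 0.29, edgeR adjusted p 0.0154). Other genes lower in MDP were Polr2l (-1.39), Lst1 (-1.18), Glp2r (-1.08), Ndufa3 (-1.01), Hcst (-1.01), Romo1 (-0.99), Aprt (-0.97) and Pet100 (-0.90), and Atp5k was at 108 ± 3.88 CPM in MDP and 217 ± 7.23 CPM in GMP (SD, n = 4). In the GRCm39 annotation Lars2 spans chromosome 9 from 123195952 to 123291731 and Chil3 spans chromosome 3 from 106054870 to 106074880. The unblocked count was 7, 1, 13 and 10 without MDP mice 1 to 4, and 10, 16, 17 and 15 without GMP mice 1 to 4, among the genes different between MDP and GMP monocytes, all kept cells. The blocked count (genes different between MDP and GMP monocytes, all kept cells, paired fit) was 1015 without mouse 1 and 964 without mouse 2, against 2018 with all 4. Without the block, Lars2, all kept cells, was not called without MDP mouse 1 (1.65) or MDP mouse 2 (1.70), and Chil3, all kept cells, was not called without MDP mouse 2 (-2.41), 3 (-2.36) or 4 (-2.31) or GMP mouse 1 (-2.44). Each of the other 3 genes was lost on leaving out any 1 of 7 of the 8 sums: Areg, all kept cells, at 1.14 to 1.32 (kept without MDP mouse 3), Spon1, all kept cells, at 1.18 to 1.33 (kept without GMP mouse 2), and Bhlhe40, all kept cells, at 0.79 to 0.88 (kept without GMP mouse 3).

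**Figure D1:**
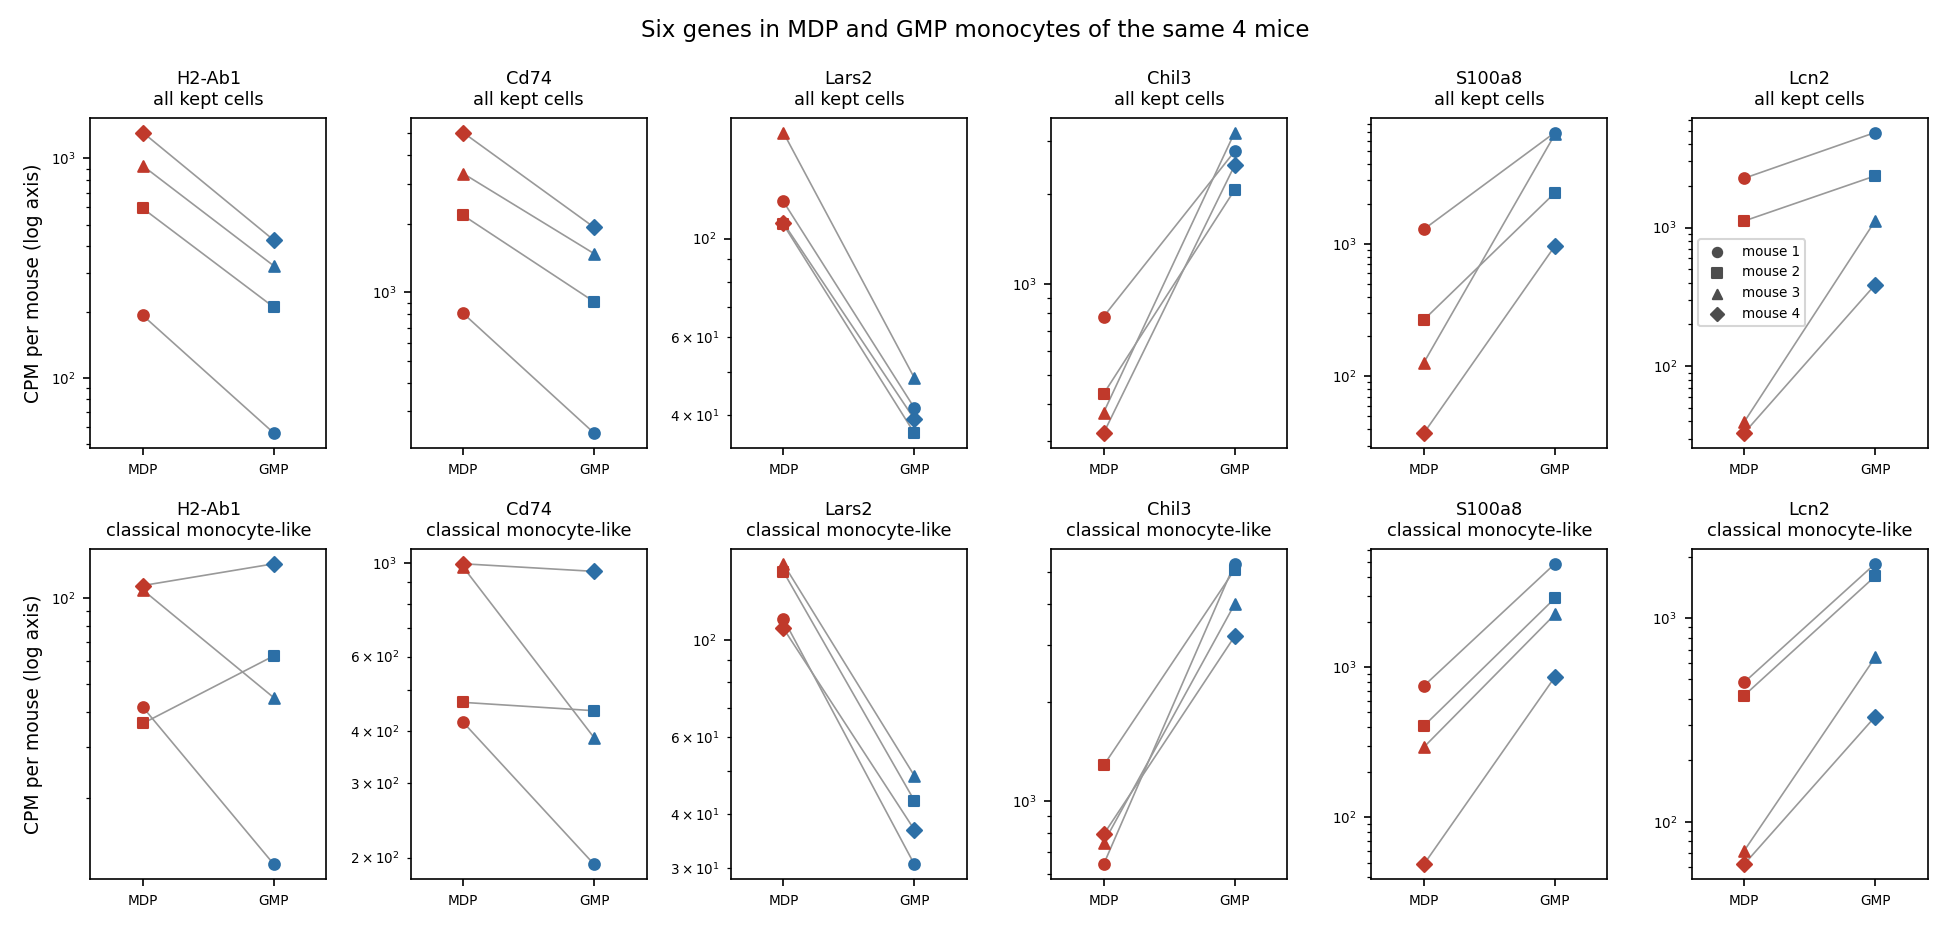
Expression of 6 genes in CPM on a log axis for each of the 4 mice, over all kept cells (top) and in the classical monocyte-like class (bottom), with a line joining the MDP and GMP values of a mouse. Over all kept cells H2-Ab1 ran from 193 to 1313 CPM in MDP and from 56.2 to 424 CPM in GMP, and within each mouse the MDP value was the higher.

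The MHC class II list, the genes that present peptides to helper T cells, moved as a group when each mouse was compared with itself. All 7 tested members were higher in MDP with the block, and all 7 also when adjusted over the list alone, with a median log2 fold change of 1.60. H2-Ab1 was at 756 ± 477 CPM in MDP and 254 ± 158 CPM in GMP (SD, n = 4; blocked log2 fold change 1.60, SE 0.06, edgeR adjusted p 2.18e-06). H2-Eb1 (1.94, SE 0.16), H2-Aa (1.79, SE 0.14) and Cd74, the invariant chain that guides class II molecules (1.39, SE 0.09), were higher in all 4 mice as well. Without the block 0 members were called by edgeR, over all genes or adjusted over the list alone, and the adjusted p was 0.427 for H2-Ab1 and 0.521 for Cd74. The camera test placed the list above other genes, with adjusted p of 1.69e-08 with the block and 0.00066 without. This was lost with an estimated correlation: adjusted p = 0.163 with an estimated correlation and the block, and adjusted p = 0.391 with an estimated correlation and no block. By fry the adjusted p was 0.00266 with the block and 0.244 without. H2-Ab1 lies on chromosome 17 from 34476663 to 34488393 and Cd74 on chromosome 18 from 60936899 to 60945731. Among cells of the classical monocyte-like and border-associated macrophage-like clusters alone, the blocked fold change turned, to -0.93 for H2-Ab1 and -0.28 for Cd74. This set leaves out a cluster led by MHC class II genes (cluster 2) and all other unnamed clusters. For mice 1 to 4, macrophage-like cells were 6 of 61, 8 of 57, 5 of 38 and 4 of 74 of its MDP cells. Of its GMP cells they were 26 of 152, 75 of 188, 34 of 509 and 48 of 887. In the blocked fit of the classical monocyte-like class alone, Cd74 was higher in MDP.

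The dendritic-cell-associated list moved with MHC class II. With the block 8 of its 12 tested members were higher and 1 lower, the same counts as when adjusted over the list alone, with a median of 0.89. Dpp4, a surface peptidase, was at 24.6 ± 18.2 CPM in MDP and 3.49 ± 3.18 CPM in GMP (SD, n = 4; blocked log2 fold change 3.08). Flt3, the cytokine receptor of dendritic cell progenitors (2.30), Kmo (2.20), Clec10a (1.28) and Bcl11a (1.51) were higher, and Cd24a (-0.73) was lower. Cd7 was counted 34 times among 13388290 MDP UMIs and 0 times among 102665494 GMP UMIs, so that it was at least 86.9-fold higher in MDP against a floor of 3 counts over the group. With Cd7 at that bound the list's median was unchanged at 0.89. Without the block 1 member was called, and 5 when adjusted over the list alone. The camera adjusted p was 4.46e-05 with the block and 0.000175 without, and it was lost in both: adjusted p = 0.163 and adjusted p = 0.0563 with an estimated correlation. By fry the adjusted p was 0.00300 with the block and 0.00486 without. Of 19 tested markers of conventional, mature and plasmacytoid dendritic cells, 11 were higher and 0 lower in MDP with the block in edgeR, among them Il4i1 (2.58), Ccr7 (2.17), Runx2 (1.14) and Wdfy4 (0.44). Of these tested markers, Clec10a, Flt3, Kmo, Dpp4, Cd7, Tcf4 and Mgl2 are also on the dendritic-cell-associated list, and Mgl2 was at -0.62 with a blocked edgeR adjusted p of 0.312.

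The neutrophil-like list, secreted and granule-associated genes of inflammatory monocytes, ran the other way. With the block 13 of its 19 tested members were lower in MDP and 1, Il1r2 (0.51), was higher, or 14 and 1 when adjusted over the list alone, with a median of -1.30. S100a8, a calcium-binding alarmin, was at 429 ± 578 CPM in MDP and 4236 ± 3002 CPM in GMP (SD, n = 4; blocked log2 fold change -3.77, SE 0.44, edgeR adjusted p 0.00042). Its partner S100a9 (-3.70, SE 0.73), the iron-scavenging protein Lcn2 (-2.14, SE 0.47), Wfdc21 (-2.50, SE 0.30) and the acute-phase protein Saa3 (-1.57, SE 0.32) were lower in all 4 mice. Without the block 1 member, Chil3, was called, and 3 when adjusted over the list alone; S100a8 then had an adjusted p of 0.272. The camera adjusted p was 3.35e-06 with the block and 7.96e-05 without, and it was lost in both: adjusted p = 0.375 and adjusted p = 0.198 with an estimated correlation. By fry the adjusted p was 0.0362 with the block and 0.0441 without. S100a8 lies on chromosome 3 from 90567118 to 90578128, S100a9 on the same chromosome from 90599931 to 90603071, and Lcn2 on chromosome 2 from 32274645 to 32278264.

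The list of azurophil and specific granule genes, which are made in neutrophil precursors, shares Lcn2, Mmp8 and Cd177 with the neutrophil-like list. With the block 6 of its 8 tested members were lower, over all genes and adjusted over the list alone, with a median of -1.71. Elane, neutrophil elastase, fell by 4.05 on the log2 scale, and Mmp9 (-2.52), Cebpe (-1.90) and Cd177 (-1.52) were also lower. Elane was at 293 CPM in GMP mouse 3 and at 4.21, 2.76 and 13.1 CPM in GMP mice 1, 2 and 4, the same mouse in which Ms4a3 reached 25.0 CPM. Without the block 0 members were called by edgeR, and 3 when adjusted over the list alone. The camera adjusted p was 0.000785 with the block and 0.00225 without, and it was lost in both: adjusted p = 0.375 and adjusted p = 0.205 with an estimated correlation. Fry did not call it either, with adjusted p of 0.0631 with the block and 0.0702 without.

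Genes of mitochondrial respiration were lower in MDP, by less. On the oxidative phosphorylation list 22 of 34 tested members were lower and 2 higher with the block, or 26 and 2 when adjusted over the list alone, with a median of -0.33. Uqcr10 was at 149 ± 7.79 CPM in MDP and 262.5 ± 3.37 CPM in GMP (SD, n = 4; unblocked log2 fold change -0.81, SE 0.08, edgeR adjusted p 0.00774). Ndufa2 (-0.66) and Uqcrq (-0.66) were also called without the block, where 5 members were lower and 0 higher in edgeR, or 17 and 1 when adjusted over the list alone. The camera adjusted p was 4.82e-08 with the block and 9.19e-11 without. Without the block the call held, with adjusted p = 0.00393 with an estimated correlation. With the block it was lost, with adjusted p = 0.163 with an estimated correlation. By fry the adjusted p was 0.0020 with the block and 5.33e-06 without. Members with transcripts under 1000 bases had a median of -0.51 (SE 0.06, 17 genes) and members of at least 1000 bases a median of -0.17 (SE 0.09, 17 genes). After a correction for transcript length the list's median was -0.10.

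**Figure D2:**
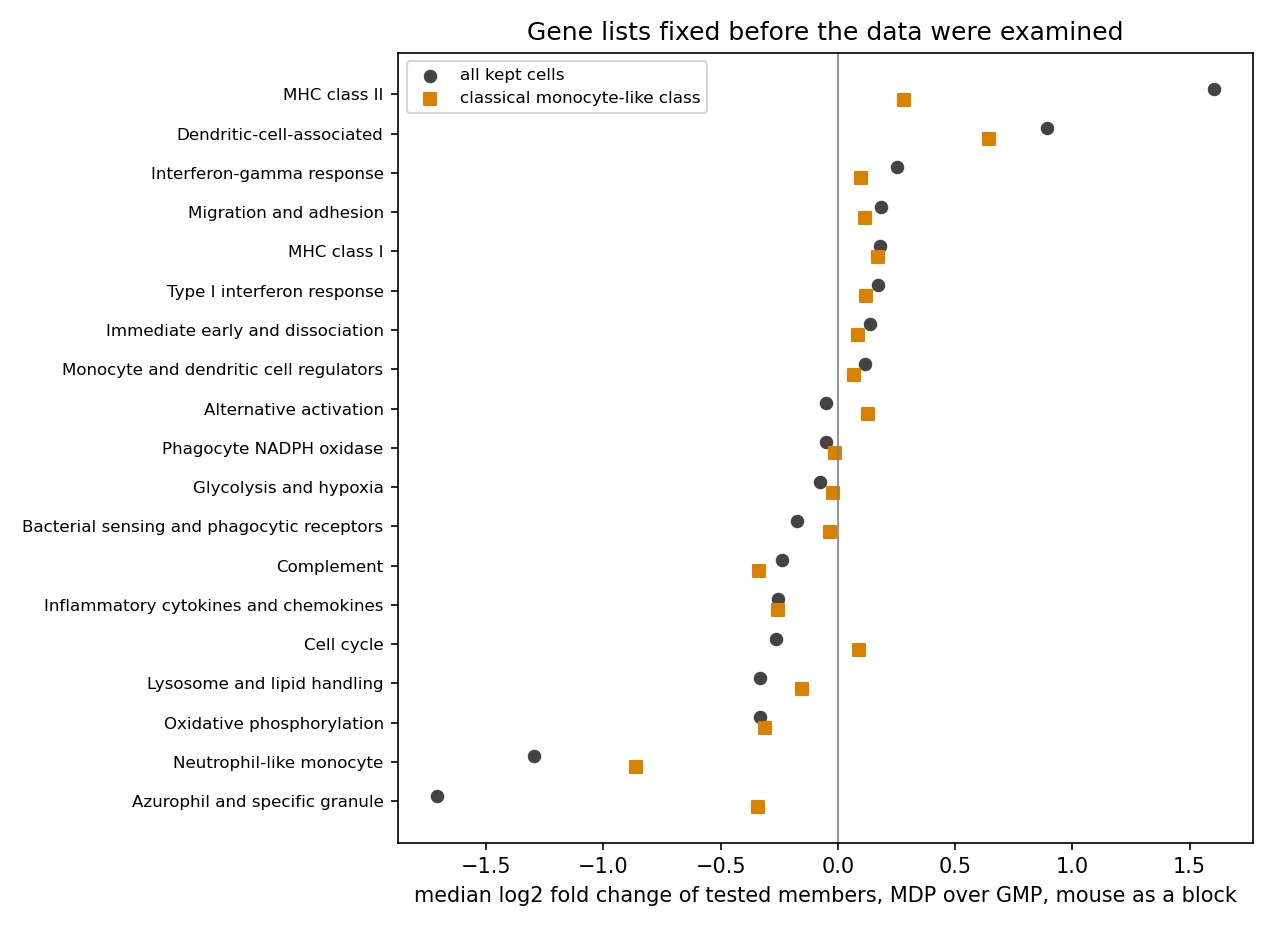
Median log2 fold change of MDP over GMP, with the mouse as a block, for the tested members of each of 19 gene lists, over all kept cells and in the classical monocyte-like class. MHC class II had a median of 1.60 over all kept cells and 0.28 in the class, and the neutrophil-like list -1.30 and -0.86.

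Lysosomal and lipid-handling genes were lower in MDP. With the block 13 of 23 tested members were lower and 0 higher in edgeR, or 14 and 1 when adjusted over the list alone, among them the secreted phosphoprotein Spp1 (-1.33), the fatty acid carrier Fabp5 (-0.95), Apoe (-0.92) and Trem2 (-0.72). The camera adjusted p was 2.64e-05 (0.00267 without the block), lost at adjusted p = 0.236 with an estimated correlation. On the complement list 6 of 11 members were lower, including C3ar1 (-0.92) and C5ar1 (-0.69), and 1 was higher, the same counts as when adjusted over the list alone (camera adjusted p 0.0127, or 0.192 without the block; adjusted p = 0.244 with an estimated correlation). Among inflammatory cytokines and chemokines 8 of 24 were lower, including Ccl7 (-1.33), Cxcl3 (-1.28) and Cxcl2 (-0.64), and 4 were higher, including Tnfsf9 (0.76) and Il6 (0.60), or 9 and 5 when adjusted over the list alone (camera adjusted p 0.0268, or 0.111 without the block; adjusted p = 0.605 with an estimated correlation). Among MHC class I genes 9 of 18 were higher and 0 lower in edgeR, including the peptide transporter Tap2 (0.76) and H2-T23 (0.53), or 11 when adjusted over the list alone (camera adjusted p 4.46e-05, or 0.000175 without the block; adjusted p = 0.244 with an estimated correlation). Interferon-gamma response genes were higher for 8 of 20 and lower for 0, the same when adjusted over the list alone, with Irgm1 (0.63) and Gbp4 (0.62) as examples (camera adjusted p 0.00106, or 0.167 without the block; adjusted p = 0.375 with an estimated correlation). Migration and adhesion genes were higher for 7 of 23 and lower for 1, or 9 and 1 when adjusted over the list alone, with Ccr7 (2.17), Cxcr4 (0.61) and Cx3cr1 (0.60) as examples (camera adjusted p 0.0252, or 0.0595 without the block; adjusted p = 0.354 with an estimated correlation). All these counts are from the blocked fit over all kept cells. Without the block 0 members of these lists were called over all genes by edgeR in those cells. The interferon-gamma direction was not kept within classes in the blocked fit. In the classical monocyte-like class 2 of 19 members were higher and 1 lower (camera adjusted p 0.297). In cluster 1, led by genes of this kind and holding a larger share of MDP cells in all 4 mice, 6 of 19 were lower and 0 higher in edgeR. Of the lysosomal list 2 of 21 members were lower in the classical class (camera adjusted p 0.121).

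Within the classical monocyte-like class, a single cluster of 1760 cells, the comparison asked whether the populations differed within 1 cell class. MDP cells of this class again held less Chil3, at 865 ± 286 CPM against 4386 ± 988 CPM in GMP (SD, n = 4; log2 fold change -2.34, SE 0.22, edgeR adjusted p 0.000626). Pglyrp1, a secreted protein that binds bacterial peptidoglycan, was at 9.35 ± 3.87 and 56.5 ± 18.3 CPM (-2.73, SE 0.36), and Wfdc17 at 741 ± 196 and 1730 ± 491 CPM (-1.23, SE 0.22). Upp1 (-1.50), Polr2l (-1.49), Gstp1 (-1.41), Lst1 (-1.19), Ly6i (-1.06), Anapc13 (-1.05) and Hcst (-1.04) were lower, and so was the arginine-degrading enzyme Arg1 (-1.73). Higher in MDP were Lars2, at 128 ± 21.8 against 39.8 ± 7.86 CPM (1.65, SE 0.18), Cmss1 (1.05), Tnfsf9, a ligand that costimulates T cells (1.02, SE 0.15), the fractalkine receptor Cx3cr1, at 61.4 ± 5.15 against 33.4 ± 6.29 CPM (0.85, SE 0.18), Prex1 (0.84), Runx2 (0.82) and Gsn (0.73). Cmss1 is also among the leading genes of an unnamed cluster of low-UMI cells. In this class Ly6c2 was at 1820 ± 433 and 1896 ± 451 CPM and Ccr2 at 555 ± 164 and 503 ± 173 CPM (SD, n = 4), and neither passed edgeR (adjusted p 0.954 and 0.907).

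In this class edgeR called 11 genes higher and 62 lower of 6832 tested without the block (420 and 468 at an unadjusted p), and 451 with it, of which 143 were higher; 73 were called in both. With a correction for transcript length the blocked split was 175 higher and 212 lower. Genes called only with the block included S100a8, at 375 ± 292 and 2719 ± 1674 CPM (blocked log2 fold change -3.00, SE 0.13, edgeR adjusted p 3.85e-10; 0.0535 without the block), S100a9 (-2.97), the chemokine Cxcl9 (-2.76), Wfdc21 (-2.48), Lcn2 (-2.19), Fpr1 (-2.04), Saa3 (-1.80) and Ccl5 (-1.67), all lower, and Htr7 (1.08), Spon1 (1.08), Ly6a (0.86) and Fmnl2 (0.85), all higher. Among the genes different between MDP and GMP monocytes, classical monocyte-like class, the unblocked count fell from 73 to 45 without MDP mouse 1, 47 without GMP mouse 1 and 45 without GMP mouse 3. The blocked count (genes different between MDP and GMP monocytes, classical monocyte-like class, paired fit) was 451, against 279 without mouse 2 and 286 without mouse 4.

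By list, the neutrophil-like genes were lower in MDP cells of this class for 10 of 17 members and higher for 0 in the blocked edgeR fit, or 12 when adjusted over the list alone, with a median of -0.86 (camera adjusted p 9.28e-09; adjusted p = 0.308 with an estimated correlation). Without the block 2 were lower (8 when adjusted over the list alone). Oxidative phosphorylation genes were lower for 17 of 34 with the block (19 when adjusted over the list alone), with a median of -0.31 (camera adjusted p 1.35e-05; adjusted p = 0.308 with an estimated correlation), and for 6 without it (17 when adjusted over the list alone), with Ndufa2 (-0.74), Cox7a2 (-0.68) and Uqcr10 (-0.66) as examples. MHC class II genes were higher for 2 of 6 with the block (3 when adjusted over the list alone), with a median of 0.28 (camera adjusted p 0.0242, or 0.159 without the block; adjusted p = 0.493 with an estimated correlation), and Cd74 was at 715 ± 315 and 495 ± 326 CPM (SD, n = 4; blocked log2 fold change 0.61, edgeR adjusted p 0.0337). MHC class I genes were higher for 4 of 17, with and without adjustment over the list alone (camera adjusted p 0.0021; adjusted p = 0.408 with an estimated correlation). On the dendritic-cell-associated list 3 of 5 were higher, Dpp4 (2.09), Clec10a (1.03) and Tcf4 (0.65), or 3 with 1 lower when adjusted over the list alone, and the camera test did not call it (adjusted p 0.0775 with the block and 0.0761 without). Fry called it, with adjusted p of 0.00428 with the block and 0.0457 without. For the neutrophil-like list the fry adjusted p were 0.0137 and 0.0955 in turn, and for MHC class II 0.289 and 0.618. For oxidative phosphorylation they were 0.0118 and 0.0457. On the azurophil list 1 of 5 was lower (4 when adjusted over the list alone; camera adjusted p 0.0021, or 0.064 without the block; adjusted p = 0.308 with an estimated correlation), and on the complement list 1 of 10 was higher and 1 lower (1 and 7 when adjusted over the list alone; camera adjusted p 0.0242, or 0.126 without the block; adjusted p = 0.308 with an estimated correlation). The MHC class II genes lead another cluster of the same cells, cluster 2, and S100a8 and S100a9 lead cluster 6, so that the choice of cluster sets part of these values.

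The only other class with enough cells was cluster 1, an unnamed cluster of 594 cells led by Cxcl10, Cxcl9 and Gbp5, genes known to be induced by interferon-gamma. In it S100a8 was at 24.3 ± 23.2 CPM in MDP and 844 ± 184 CPM in GMP (SD, n = 4; log2 fold change -5.34, SE 0.47, edgeR adjusted p 0.00054). The lipid carrier Apoe was at 115 ± 38.0 and 454 ± 69.5 CPM. Apoc2, another lipid carrier (-1.60), the complement genes C1qc (-2.12) and C5ar1 (-1.25), the antiprotease Slpi (-1.67), Slc28a2 (-1.90) and Gm10076 (-1.41) were the other genes lower in MDP. These were the 8 called without the block, of 4818 tested, with 0 higher in edgeR (166 higher and 235 lower at an unadjusted p; 10 higher and 36 lower by DESeq2); with the block 38 were higher and 156 lower. The count without the block was 4, 5, 17, 13, 3, 3 and 3 without MDP mice 1, 2 and 4 and GMP mice 1 to 4, among the genes different between MDP and GMP monocytes, each other class. Whether the population effect differed between cluster 1 and the classical monocyte-like class was tested by the interaction: edgeR called 0 of 6512 genes without the block (180 at an unadjusted p; no other tool was run) and 1 gene with it, S100a8.

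Shares of cells in each class were compared to describe what the sort collected. The classical monocyte-like class held 23.3 ± 14.3% of MDP cells and 32.1 ± 35.4% of GMP cells (SD, n = 4; exact permutation p 0.657, two-sided, adjusted p 1, higher in MDP in 2 of 4 mice). Border-associated macrophage-like cells were at 2.58 ± 1.86% and 2.52 ± 1.68%, and fibroblast-like cells at 1.01 ± 1.48% and 0.458 ± 0.217% (adjusted p 1 each, exact permutation test). For mice 1 to 4, the classical monocyte-like class held 11.6, 10.2, 35.1 and 36.3% of MDP cells and 2.55, 2.67, 49.6 and 73.6% of GMP cells. It was thus higher in MDP in mice 1 and 2 and lower in MDP in mice 3 and 4. The 10 unnamed clusters held 73.1 ± 16.4% and 64.9 ± 37.2% together. For mice 1 to 4, cluster 1 held 14.6, 23.2, 33.0 and 15.5% of MDP cells and 0.547, 1.89, 21.8 and 3.16% of GMP cells. Cluster 2, led by MHC class II genes, held 1.48, 7.05, 19.1 and 42.5% of MDP cells and 0.446, 2.72, 9.82 and 11.8% of GMP cells. Cluster 6, led by S100a9 and S100a8, held 5.92, 3.11, 0 and 0% of MDP cells and 14.3, 9.56, 8.57 and 1.58% of GMP cells. Cxcl10, H2-Aa and S100a9, which are among the leading genes of these 3 clusters in turn, themselves differed between the populations in the blocked edgeR fit, so the cluster sizes were not tested. In clusters built without the genes called between the populations, the classical monocyte-like class held 36.9 ± 28.0% and 38.6 ± 38.7% (exact permutation p 0.943, adjusted p 1), and a non-classical monocyte-like class 5.52 ± 4.73% and 3.25 ± 1.61% (exact permutation p 0.514, adjusted p 1). At resolution 1.2 a non-classical monocyte-like cluster held 0.157 ± 0.199% of MDP and 0.859 ± 0.285% of GMP cells, lower in MDP in all 4 mice (exact permutation p 0.0286, adjusted p 0.171). With the stricter cell filter such a cluster held 0.172 ± 0.343% and 0.478 ± 0.565% (exact permutation p 0.543, adjusted p 0.914). The direction for this class thus depends on the clustering. The smallest p the 8 shares allow is 0.0286, and the sort gates set the shares in part. The difference for classical monocyte-like cells, MDP minus GMP, was -8.82 percentage points, and 5.01 without GMP mouse 4.

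**Figure D3:**
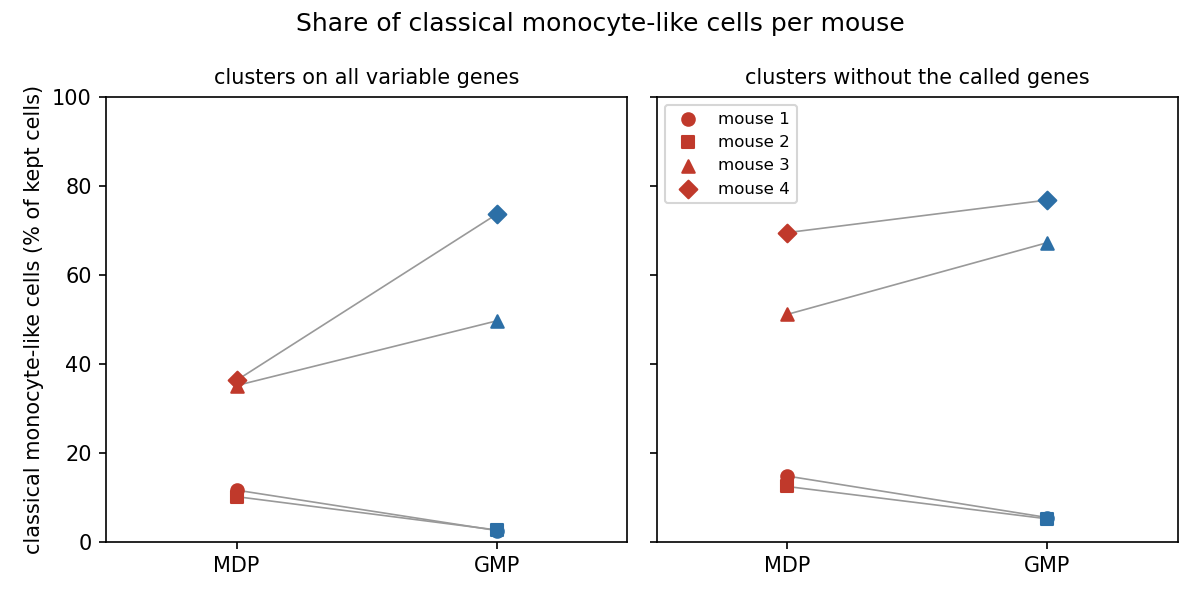
Share of kept cells in the classical monocyte-like class, in percent, for each of the 4 mice and both populations, from clusters built with all variable genes and from clusters built without the called genes. With all variable genes the GMP values ran from 2.55 to 73.6% and the MDP values from 10.2 to 36.3%.

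The share of classical monocyte-like cells with a UMI was read after thinning each cell to 2000 UMIs, which left out 26 shallower cells. Saa3 was found in 61.4 ± 15.9% of MDP and 96.8 ± 4.33% of GMP cells (SD, n = 4; exact permutation p 0.0286, the smallest possible, adjusted p 0.171, lower in MDP in all 4 mice), and in 85.7 and 99.9% unthinned. It was also found in 90.9% of fibroblast-like and 89.4% of border-associated macrophage-like cells, at a median depth of 11141 UMIs in fibroblast-like against 8014 UMIs in classical monocyte-like cells. In the MDP capture Saa3 was at 16355 CPM in border-associated macrophage-like and 2794.5 CPM in classical monocyte-like cells, so no background level was read from the former, and how much free RNA adds to the Saa3 shares is open. Flt3 was found in 3.12 ± 2.62% and 0.933 ± 0.555% (exact permutation p 0.2, adjusted p 0.4; 14.4 and 3.51% unthinned), with 0% in fibroblast-like and 0.503% in border-associated macrophage-like cells. Cd177 was found in 0.735 ± 1.47% and 3.90 ± 1.86% (exact permutation p 0.0571, adjusted p 0.171; 8.89 and 12.7% unthinned), Mmp8 in 34.5 ± 15.6% and 42.2 ± 15.9% (p 0.514 by the exact test, adjusted p 0.771; 66.5 and 68.5% unthinned) and Slamf7 in 2.20 ± 0.640% and 2.50 ± 1.05% (p 0.686 by the exact test, adjusted p 0.823; 8.67 and 7.38% unthinned), with 4.55, 0 and 0% for Mmp8, Cd177 and Slamf7 in fibroblast-like cells. In border-associated macrophage-like cells Slamf7 was found in 10.05% and Mmp8 in 3.02%. For Slamf7 no background level was read from these cells or from the 44 fibroblast-like cells. Cd209a was found in 0% of both. None of the 6 genes passed after adjustment. A gene alone at the smallest possible p reaches an adjusted p of only 0.171 in this test, as Saa3 did, so this result says little.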

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

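The tests of ribosomal protein genes, free RNA, cluster mix with the clusters of the report, and dendritic cells were chosen after the result was seen; those of transcript length, long oxidative phosphorylation genes, clusters built without the called genes and splits of the samples were not.

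Genes with short transcripts were lower in MDP than in GMP monocytes. Over genes outside the ribosomal protein and oxidative phosphorylation families, the blocked log2 fold change rose with transcript length (Spearman rho 0.234 across genes, which are not independent replicates; 0.150 in the classical monocyte-like class), as a loss of short transcripts in the MDP capture would give. Long members decide less: transcripts of at least 1000 bases had a median of -0.08 (-0.0822, SE 0.06) among ribosomal protein genes and -0.17 (-0.167, SE 0.09) on the oxidative phosphorylation list, against -0.03 (SE 0.06) and -0.08 (SE 0.10) in the classical monocyte-like class, so that a lower expression of either family over all kept cells stays open. Capture and population are the same split here, so a technical loss and a difference between the populations cannot be told apart. A candidate explanation for Polr2l, Atp5k and Uqcr10 is therefore the capture, and no biological one was excluded.

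Granule and alarmin genes were lower in MDP. Free RNA in the GMP capture was weighed by taking the level of border-associated macrophage-like cells from the GMP classical monocyte-like level: the called members were then at a median log2 ratio of GMP over MDP of 0.0691, but 4 of these 10 members (Lcn2, Saa3, Wfdc17 and Fpr1) are at or above the classical level in those cells in the MDP capture too, so that the subtraction takes away more than free RNA. For the 6 members below it in both captures the median ratio was 2.14. That condition favours members that keep a remainder after the subtraction, so the median decides nothing for the list. Fpr2 (0.0655) and Hp (0.0728) were about level. S100a8 (2.47), Chil3 (2.24), Wfdc21 (2.20) and S100a9 (2.08) stayed higher in GMP, which argues against free RNA as the only cause for these genes alone. Cells matched by cluster within each mouse kept 0.486 of the list's median, and 0.848 with clusters built without the called genes; the latter passes the bound set beforehand for a mix not being the cause, but 15 of the 19 members had been left out of that clustering, which then cannot part cells that differ mainly in them. In cluster 6, with mice summed, Ngp, Camp, Elane, Mpo and Prtn3 were at 679, 689, 213, 29.1 and 345 CPM in GMP cells. In the 43 MDP cells of this cluster they were at 0, 0, 20.8, 3.78 and 274 CPM. These MDP cells came from mice 1 and 2 only (28 and 15 cells). The GMP cells came from mice 1 to 4 (705, 404, 82 and 18 cells), and over all kept cells Elane was by far highest in GMP mouse 3. The summed values thus do not compare the same mice. Ngp, Camp, Elane, Mpo and Prtn3 are markers of neutrophil precursors, and whether such cells in the GMP gate add to the granule genes was not tested. The mix of cells, the capture and a difference between the lineages may each contribute and stay open.

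MHC class II genes were higher in MDP, and dendritic cells in the MDP gate could bring them: 0.579 of the tested dendritic cell markers outside the list were higher in MDP (11 of 19 tested, of 32 listed), with Tcf4 at 138 ± 11.6 CPM in MDP and 103 ± 18.4 CPM in GMP and Dpp4 at 24.6 ± 18.2 and 3.49 ± 3.18 CPM (SD, n = 4). The list kept 0.175 of its median in the classical monocyte-like class and 0.361 in cells matched by cluster, while in cluster 1 its median was 1.12 with 5 of 6 members higher, but cluster 2 is itself led by H2-Aa and Cd74, so these values are set in part by the clustering. The dendritic-cell-associated list did not drop alike in the class, where it had a median of 0.65 over 5 tested members with 3 higher, against 0.89 over 12 in all kept cells, but the members tested differ and decide nothing. With clusters built without the called genes it kept 0.941, which passes the bound set beforehand, yet 7 of 7 members had been left out of that clustering. No clustering named a dendritic cell cluster. With mice summed, H2-Ab1 in clusters 3, 4, 5, 7 and 9 was at 167, 163, 989, 752 and 343 CPM in MDP cells, which came from mice 1 and 2. GMP cells there held 54.1, 65.0, 414, 213 and 75.8 CPM. Zbtb46, a dendritic cell marker, was at 0, 0, 0, 1.37 and 0 CPM in these MDP cells. With 80, 100, 34, 66 and 62 such cells, the 0 values bound little. In clusters 1 and 2 Zbtb46 was at 9.37 and 9.41 CPM in MDP cells and at 3.09 and 0.751 CPM in GMP cells. In cluster 6 and the classical class it was at 0 and 0.484 CPM in MDP cells and at 0.450 and 0.477 CPM in GMP cells. Summed in the same way, H2-Ab1 in MDP and GMP cells was at 1938 and 1937 CPM in cluster 2 and at 24.6 and 25.0 CPM in cluster 6. In the classical class it was at 76.9 and 81.3 CPM. The mice weigh unequally in these sums, which do not compare a mouse with itself, so no likeness of the populations is read from them. Admixed dendritic cells, the capture and higher expression in MDP monocytes remain open.

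Whether chance can be excluded was read from other splits of the 8 sums. Without the block, 2 of 35 splits called as many genes as the real one over all kept cells (62; highest other 2538), 2 of 35 in the classical monocyte-like class (73; 175) and 3 of 35 in cluster 1 (8; 70), so that chance was not excluded. The split with 2538 calls set mice 1 and 2 against mice 3 and 4 and called several times the real count, which points to a structure between mice. For the interaction 35 of 35 splits reached the real count of 0 (highest other 1), and for the lists 9 of 35 over all kept cells (8; 9) and 25 of 35 in the class (3; 7). In the fit with the replicate block only 8 exchanges exist, too few for a share under 0.05: 1 of 8 reached the real count, which was 2018 over all kept cells and 451 in the class, with 0 as the highest other in each. Without the block, the other 7 splits that part all 4 pairs called 0 genes by edgeR over all kept cells, in the class and in cluster 1.

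Single sums stood apart from the other 3 of their population in 11 of 176 tests, where chance gives about 1 in 20. Over all kept cells, with the gap as a share of the range, these were Areg in GMP mouse 3 (lowest, 0.859), Atp5k in MDP mouse 4 (lowest, 0.940), Bhlhe40 in GMP mouse 3 (highest, 0.836), Cxcl10 in MDP mouse 3 (highest, 0.877) and GMP mouse 3 (highest, 0.912), and Cxcl2 in GMP mouse 3 (lowest, 0.866). In the classical monocyte-like class they were Arg1 in GMP mouse 3 (highest, 0.920), B2m in GMP mouse 4 (highest, 0.869), Gsn in GMP mouse 1 (lowest, 0.907), Isg15 in GMP mouse 1 (lowest, 0.874) and Runx2 in MDP mouse 1 (highest, 0.916).

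The population effect on S100a8 differed between cluster 1 and the classical monocyte-like class by -2.53 on the log2 scale in the interaction test with the replicate block (edgeR adjusted p 0.0157); without the block the difference was -2.55 with an adjusted p of 1.00.

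The 8 tags assigned to no mouse gave 242443 counts in the MDP capture and 4028357 in the GMP capture. Among deposited cells, 31 of MDP mouse 1, 1 of MDP mouse 2, 1 of MDP mouse 3, 9 and 1 of GMP mouse 3, and 1 and 1 of GMP mouse 4 had such a tag as their highest.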

How the results depend on the processing

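Alternatives with the mouse as a block, other than the block itself, cells matched by cluster, the top 5% of doublet scores and the removal of doubtful clusters were chosen after seeing the data. Unless a construction is named, the cause was not tested.

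For genes different between MDP and GMP monocytes, all kept cells, 62 were called. DESeq2 gave 325, limma voom 339, the replicate block 2018 and leaving out a sum 1 to 17. Equal cells and depth gave 29, clusters named monocyte-like or macrophage-like 36 and matched cells 20. These last 3 use fewer cells. The named clusters and matched cells also hold another mix of clusters, so the 2 changes cannot be told apart there. For genes different between MDP and GMP monocytes, all kept cells, paired fit, 2018 became 62 with no replicate block, 964 to 2085 without a mouse, 258 in the named clusters and 873 in matched cells; 543 higher and 845 lower were called when matched by clusters built without the called genes. For genes different between MDP and GMP monocytes, classical monocyte-like class, 73 became 148 with DESeq2, 309 with no low-count filter, 451 with the replicate block, 45 to 62 without a sum, 14 with the stricter cell filter (MDP mice 1 and 2 then had too few cells), 197 with called doublets kept, 204 at resolution 0.5 and 32 at 1.2. For genes different between MDP and GMP monocytes, classical monocyte-like class, paired fit, 451 became 73 with no replicate block, 279 to 309 without a mouse, 234 with DESeq2, 298 with the stricter filter, 1010 with doublets kept, 927 at resolution 0.5 and 209 at 1.2; keeping doublets or changing the resolution redraws the clusters, and at 1.2 MDP mouse 2, with 19 cells, also fell under the minimum of 20, so that its sum, and with the block the whole mouse, was left out. For genes different between MDP and GMP monocytes, each other class, 8 became 46 with DESeq2, 194 with the replicate block, 157 with no filter and 3 to 17 without a sum. The interaction count of 0 became 1 with the replicate block and stayed 0 without any sum. Of gene lists over all kept cells, 8 were called, 1 with an estimated correlation and 14 with the replicate block, of which 0 with an estimated correlation. In the class 3 were called, 0 with an estimated correlation, 6 with the replicate block, of which 0 with an estimated correlation, and 4 to 8 without a sum.

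Differences of shares, MDP minus GMP in percentage points, turned for border-associated macrophage-like cells (main 0.0640; -0.849, -0.599 and -0.183 without MDP mouse 3, GMP mouse 1 and GMP mouse 2; highest 0.629), classical monocyte-like cells (main -8.82; 1.82 at resolution 0.5, 5.84 with doublets kept and 5.01 without GMP mouse 4; lowest -18.7), fibroblast-like cells (main 0.548; -0.180 without MDP mouse 3; highest 0.884), the unnamed clusters together (main 8.21; -6.21 without GMP mouse 4; highest 18.8) and cells with a Slamf7 UMI (main -0.296; 1.29 not thinned and 0.0694 without GMP mouse 3; lowest -0.646). Non-classical monocyte-like cells, not named in the main clusters, turned from 2.28 in clusters built without the called genes to -0.703 at resolution 1.2 and -0.307 with the stricter filter. For Flt3 the range without a sum was 1.21 to 3.23, the latter without MDP mouse 4 at an unadjusted exact p of 0.0286, and for Saa3 -41.0 to -29.1. For Mmp8 (main -7.66) it was -15.3 to -0.558, with -11.7 and -0.558 without MDP mice 1 and 4 and -3.13 and -15.3 without GMP mice 2 and 4, and -0.406 at 1000 UMIs and -1.94 not thinned; Cd177 (main -3.17) was at -1.47 at 1000 UMIs. In the blocked fit, Cd74 turned to -0.28, H2-Aa to -1.06, H2-Ab1 to -0.93 and H2-Eb1 to -1.47 in the classical monocyte-like and border-associated macrophage-like clusters alone, which leave out cluster 2. Cxcl10 turned to -0.43 in matched cells, and Ttr to 0.37 with equal cells and depth and 0.21 in matched cells. Among named genes 0 of 38 and 6 of 52 turned over all kept cells without and with the block, and 0 of 43 and 0 of 53 in the class.

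Without the block, 62, 73 and 8 genes kept the call they had with it (all kept cells, the class and cluster 1), and every other gene called with it, list members included, was not called; camera calls printed with 1 value were the same in both fits. Other size factors, 10 CPM, no cell filter, doublets kept, the top 5% of doublet scores removed and the low-UMI, macrophage-like and fibroblast-like clusters removed left the count over all kept cells within 1.5 times 62. UMIs were fewest in MDP mouse 3 over all kept cells and in GMP mouse 1 in cluster 1.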

Other observations

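The list tests in this part, with and without the block, were set beforehand; the genes named in cluster 1 were chosen after their values were seen.

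Lists not described above moved little or both ways over all kept cells in the blocked edgeR fit. Type I interferon response genes were higher for 6 of 25 and lower for 1, the same when adjusted over the list alone (camera adjusted p 0.072). Bacterial sensing and phagocytic receptors were lower for 8 of 30 and higher for 3 (10 and 3 when adjusted over the list alone; camera adjusted p 0.072), with Fcer1g, a signalling chain of Fc receptors, at 4285 ± 1174.5 CPM in MDP and 5822 ± 1734 CPM in GMP (SD, n = 4; log2 fold change -0.44). Immediate early and dissociation genes were higher for 7 of 25 and lower for 3 (9 and 3 when adjusted over the list alone; camera adjusted p 0.0293, or 0.111 without the block; adjusted p = 0.244 with an estimated correlation), led by Btg2 (0.75) and Zfp36 (0.55). Regulators of monocytes and dendritic cells were higher for 8 of 21 and lower for 3 (9 and 3 when adjusted over the list alone; camera adjusted p 0.0268, or 0.0345 without the block; adjusted p = 0.244 with an estimated correlation), with Bhlhe40 (0.88) and Relb (0.45) higher and Cebpe (-1.90), a factor of granule gene expression, lower. The phagocyte NADPH oxidase list had 1 higher and 2 lower of 7 (1 and 3 when adjusted over the list alone; camera adjusted p 0.516), and glycolysis and hypoxia 3 higher and 5 lower of 24 (3 and 7 when adjusted over the list alone; camera adjusted p 0.359). Alternative activation had 3 higher and 1 lower of 14 (3 and 2 when adjusted over the list alone; camera adjusted p 0.545), with a median of -0.05 and a mean of -0.12 but an upward test direction. Cell cycle genes had 1 lower of 27, Hmgb2 (-0.44), and 0 higher in edgeR (0 when adjusted over the list alone; camera adjusted p 0.0299, or 0.111 without the block; adjusted p = 0.667 with an estimated correlation).

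In cluster 1, 5 of 6 tested MHC class II genes were higher in MDP in the blocked edgeR fit (6 when adjusted over the list alone), with a median of 1.12, among them H2-DMb1 (1.46) and H2-Eb1 (1.35; camera adjusted p 7.18e-06; adjusted p = 0.346 with an estimated correlation). Neutrophil-like genes were lower for 7 of 15 (8, with 1 higher, when adjusted over the list alone), with Chil3 at -4.67 and Lcn2 at -1.84 (camera adjusted p 1.75e-06; adjusted p = 0.346 with an estimated correlation). Complement genes were lower for 5 of 9 (5, with 1 higher, when adjusted over the list alone), with a median of -0.90 (camera adjusted p 0.00112; adjusted p = 0.346 with an estimated correlation), and inflammatory cytokines and chemokines for 6 of 20, with 1 higher (11 and 1 when adjusted over the list alone; camera adjusted p 0.000171; adjusted p = 0.346 with an estimated correlation). Interferon-gamma response genes, which lead this cluster, were lower for 6 of 19 (9, with 1 higher, when adjusted over the list alone; camera adjusted p 5.06e-06; adjusted p = 0.346 with an estimated correlation). Without the block the camera adjusted p of these 5 lists were 3.59e-05, 7.84e-07, 0.00129, 0.00482 and 0.00282. These calls too were lost: adjusted p = 0.312, 0.141, 0.312, 0.390 and 0.549 with an estimated correlation and no block. With the block, camera also placed type I interferon response genes lower (adjusted p 5.06e-06), with 1 of 24 called lower, or 10 when adjusted over the list alone. By camera, lysosome (adjusted p 0.00209), oxidative phosphorylation (0.00265) and bacterial sensing genes (0.0116) were lower and immediate early genes (0.0410) higher. All were lost: adjusted p = 0.385, 0.346, 0.346, 0.346 and 0.510 with an estimated correlation. Dpp4 (2.06), Ccnd1 (2.15) and Kdr (2.97) were among the 38 genes higher in MDP.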
